A study of Mus musculus with 8 samples.

How the data were processed

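RNA was measured in 8 libraries from mouse lenses at embryonic day 14.5, 4 of control lenses and 4 labelled Mettl3 CKO, each group with replicates a to d. Per the labels' protocols, RNA was extracted with TRIzol, polyadenylated RNA was selected and libraries were made with an NEBNext Ultra RNA kit. The labels name no Cre driver and do not say how many lenses or animals each library holds. Per the submitters' processing notes, CASAVA, HISAT2 and featureCounts were used on genome build mm10, with no versions. The annotation release and the strand setting of the counting are not given in the sources used here. The authors deposited 1 table of read counts per Ensembl gene, whole numbers that were not normalised, for all 8 libraries.

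The table held 43432 gene IDs, of which 42548 were matched to the GENCODE M21 annotation of mm10 for symbols, coordinates and biotypes. The 884 unmatched IDs took at most 0.105% of the counts of any library and were kept in the tests under their IDs. No row named anything other than a gene. Library totals lay between 19110170 and 56098211 counts, and counting error is therefore small for all but rare transcripts. Libraries of the same genotype differed by far more than sampling noise (chi-square per degree of freedom between 15.3 and 102), so none was treated as a repeat of another. This comparison with counting noise alone cannot tell separate animals from separate preparations of the same RNA. Because strand use is unknown, reads from overlapping and antisense genes cannot be told apart, and close copies such as the gamma crystallins, or Rbmxl1 and Rbmx, can share reads.

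Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15, by genotype), which left 16241 genes and removed 27191. Library sizes were scaled by TMM, and the robust quasi-likelihood F-test was fitted with the set (replicates a and b, or c and d) and genotype as terms. The set was included because the records of the 2 pairs of replicates stand apart in the series, although no label calls them batches. P-values were adjusted by the Benjamini-Hochberg method and genes with an adjusted p under 0.05 were called changed. Every adjusted p of a gene in the text comes from this edgeR test unless another tool is named. CPM values are counts scaled to a common library size after TMM, with a prior count of 2 where they are on the log2 scale for lists. A second fit with the interaction of genotype and set tested whether the genotype effect differed between sets. The effect within each set came from separate fits of the libraries of that set, with genotype as the only term. The correlation of these effects across genes has no p-value.

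Before the data were examined, the design, the alternatives, 30 gene lists and the rule for naming genes were fixed. The named genes were Mettl3, the 12 largest rises and 12 largest falls and the 5 smallest p-values in each direction among changed genes with a mean of at least 5 CPM in 1 genotype, the same sign in both sets and an established symbol, up to 4 members of each list, and 21 lens and m6A genes given whatever their result. Genes named outside this rule are said to have been chosen after their values were seen. Some results that the rule covers are not reported here. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, with adjustment over the 30 lists, and camera with a correlation estimated for each list and fry were run beside it. With the preset correlation 12 lists were called, 7 higher and 5 lower, with an estimated correlation none was, and fry called 9. Mettl3, the crystallin share of counts and the mean log2 CPM of the lists were compared by two-sided exact permutation tests of 4 against 4 libraries, for which the smallest possible p is 0.0286. No list passed this permutation test after adjustment over the 30 lists (smallest adjusted p = 0.107), which the smallest possible p makes hard to pass. Intervals of a library's crystallin share cover counting error only and are not printed, since the spread between libraries is far wider.

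Simulated counts with the means and library sizes of these libraries were used to test the code. Among 15854 simulated genes with 200 changed, edgeR recovered 16.4% of 1.5-fold, 64.2% of 2-fold and 75.8% of 4-fold changes, and 7.14% of its calls were false. A simulated moved list had a camera adjusted p of 2.53e-05 and 0 of 30 unmoved lists were called. The simulated genes were drawn independently and the lists at random. Estimated correlations of the real lists went from -0.05 (cyclin-dependent kinase inhibitors) to 0.93 (endothelium and pericytes). The simulation therefore does not give the rate of false camera calls for lists whose members vary together. In the simulated interaction, over 15824 genes, 66% of 4-fold changes confined to 1 set were recovered, among 100 changed genes, with 10 false calls.

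The alternatives were other scalings (RLE, upper quartile, TMM without crystallin and erythroid genes), other filters, DESeq2 1.42.0, limma-voom, fits without the set term, with the replicate letter in its place, without robust estimation or with 1 surrogate variable (sva 3.50.0), each set alone, stricter thresholds, and leaving out each library in turn. Chosen after the data were seen were the removal of each library's trends on transcript length and GC content, the fit of the same 14032 protein-coding genes with the trends left in and the omission of control a with CKO c. To ask whether chance groupings give as many calls, the fit was repeated on 34 splits of the 8 libraries into 4 and 4. The split that follows the sets was left out, since the set term then leaves nothing to fit. For gene architecture, the longest coding stretch within 1 exon and the density of DRACH motifs (the sequence context of m6A) in sequence over 200 nt from an exon junction were taken from protein-coding transcripts of the annotation. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.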

Results

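Gene expression was measured by RNA sequencing of polyadenylated RNA from mouse lenses at embryonic day 14.5. At this stage the lens vesicle has been filled by primary fibers, and epithelial cells at the equator leave the cell cycle and elongate into secondary fibers. The libraries were 4 from control lenses and 4 labelled Mettl3 CKO, a conditional knockout of the gene for the catalytic subunit of the enzyme complex that writes N6-methyladenosine (m6A) on mRNA. The comparison asked which transcripts differ when Mettl3 is lost, in a series whose stated subject is the differentiation of secondary fiber cells. Each genotype has replicates a to d. Replicates a and b (set 1) and replicates c and d (set 2) stand in separate runs of the series records, so the set was a term in the model. The control libraries held 25662135, 24374038, 45310168 and 56098211 gene counts in replicates a to d, and the CKO libraries 19110170, 24499316, 51142336 and 47363760. No source used here says that the libraries came from separate animals, so the p-values measure the spread between these libraries, which may be partly technical. The common biological coefficient of variation, 1 value shared by all genes, was 23.1%.

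Mettl3 transcript was lower in every CKO library than in any control library. Mettl3 (ENSMUSG00000022160, mm10 chromosome 14, 52294841 to 52305128, minus strand, protein coding) had a mean of 24.8 CPM ± 2.94 (SD, n = 4) in controls and 12.4 CPM ± 3.25 (SD, n = 4) in CKO lenses. The controls stood at 28.4, 25.4, 23.8 and 21.4 CPM and the CKO libraries at 13.4, 15.9, 8.11 and 12.2 CPM in replicates a to d. The log2 fold change was -1.02 (SE 0.15, edgeR quasi-likelihood adjusted p = 0.00259), with -0.88 in set 1 and -1.16 in set 2. A two-sided exact permutation test of log2 CPM gave p = 0.0286, the smallest value that the 70 splits of 4 against 4 can give. Gene-level counts do not show which exons the remaining reads cover, so transcript lacking a deleted part is counted here as Mettl3.

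Some other genes of the m6A pathway rose in CKO lenses, 3 of the writer complex and 3 readers. Over the writer complex the median was 0.32 (0.11 in set 1 and 0.41 in set 2), and over readers and erasers 0.02, where 5 of 13 fitted values lay below 0. Among 8 members of the writer complex, Rbm15 rose by 1.12 on the log2 scale (SE 0.15, adjusted p = 0.00201) and Rbm15b by 0.86 (SE 0.13, adjusted p = 0.00267). These encode RNA-binding adaptors that bring the complex to its targets. Wtap, a scaffold subunit, rose by 0.33 (SE 0.09, adjusted p = 0.0361). Mettl14, the partner of Mettl3 in the catalytic dimer, did not pass (log2 fold change -0.24, adjusted p = 0.202). Adjusted over the list alone, 5 members rose and 1 fell, against 3 and 1 over all genes tested. Of 13 readers and erasers, the reader genes Ythdf2 (1.24, SE 0.12, adjusted p = 0.000437), Ythdf1 (0.79, SE 0.11, adjusted p = 0.00254) and Ythdc1 (0.36, SE 0.10, adjusted p = 0.0496) rose and 10 did not pass, with the same 3 rises adjusted over the list alone. The writer list was called as higher by the gene set test camera (adjusted p = 0.0374), as was the reader and eraser list (adjusted p = 0.0212). With an estimated correlation the adjusted p was 0.487 for the first and 0.602 for the second. The call for Ythdc1 ended without any 1 of the 8 libraries (adjusted p 0.0543 to 0.172), and that for Wtap without any of them but control c (adjusted p up to 0.135). The writer list was no longer called without control c, control d, CKO c or CKO d (adjusted p up to 0.112), and the reader and eraser list without control c or CKO c (adjusted p up to 0.218).

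**Figure D1:**
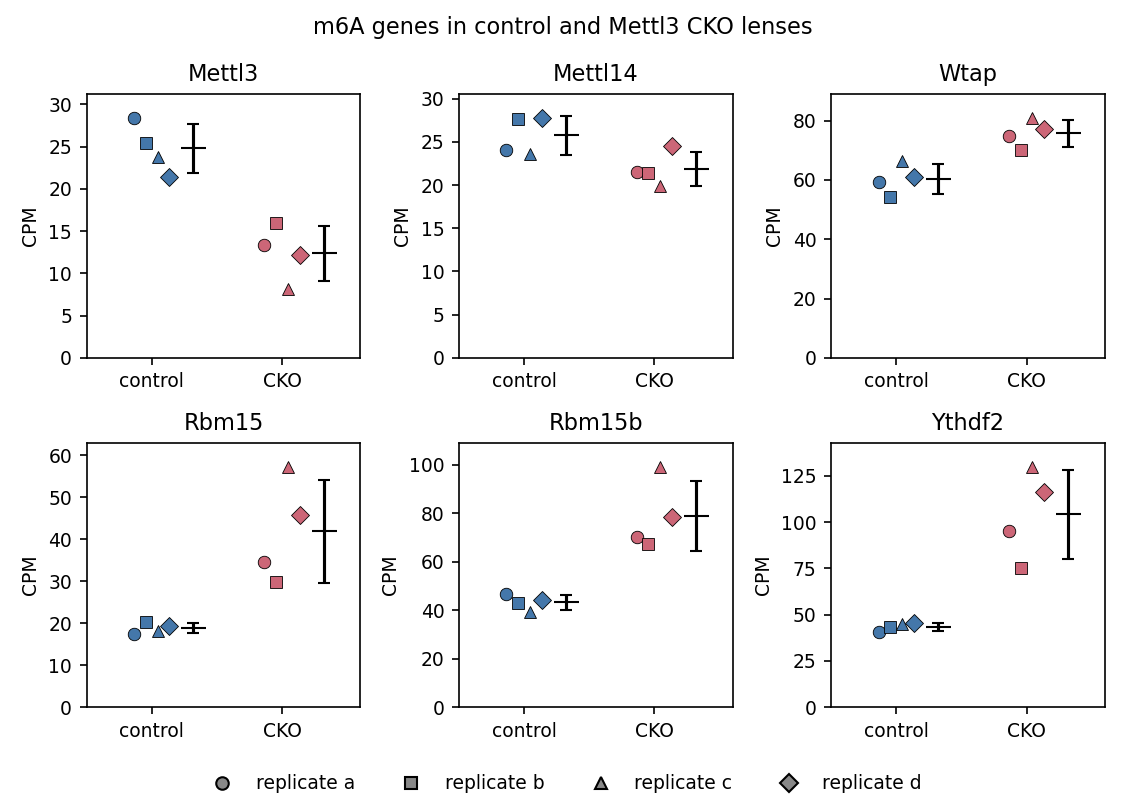
Expression of 6 m6A genes in CPM (linear axis from 0), with 1 point per library, the marker giving the replicate letter, and the bar giving the mean ± SD of the 4 libraries of a genotype. Mettl3 lies between 21.4 and 28.4 CPM in controls and between 8.11 and 15.9 CPM in CKO lenses, while Rbm15, Rbm15b and Ythdf2 lie higher in every CKO library than in any control.

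Across the transcriptome, 1706 of 16241 tested genes changed at an adjusted p under 0.05, 1055 higher and 651 lower in CKO lenses. A change of over 2-fold was fitted for 253 of the genes that rose and 74 of those that fell. The largest rise was that of Tgm7 (chromosome 2, 121093565 to 121109795), a transglutaminase gene, from 0.176 CPM ± 0.101 (SD, n = 4) to 5.83 CPM ± 3.18 (SD, n = 4), a log2 fold change of 5.05 (SE 0.52, adjusted p = 0.000691). Aldh1b1, a mitochondrial aldehyde dehydrogenase gene, rose by 2.45 (SE 0.28), the transcription factor gene Sox21 by 2.32 (SE 0.27) and Gfra2, which encodes a co-receptor for neurturin, by 2.13 (SE 0.18). Dyrk3, Col20a1, Crabp2, Mroh2a, Aunip, Lingo1, Tnfsf9 and Ngfr rose by between 1.77 and 2.11. The smallest p-values among rises were those of Mroh2a, Rbmxl1, Riox1, Plekho1 and Cdca4, each with an adjusted p of 0.000184. Rbmxl1 is an intron-poor relative of Rbmx, and reads shared between such copies make its value uncertain.

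The largest falls were those of Gcg, the preproglucagon gene (log2 fold change -2.57, SE 0.58), and Nupr1, a stress-responsive nuclear protein gene (-2.42, SE 0.40). Gcg went from 44.1 CPM ± 5.9 to 7.68 CPM ± 4.14 and Nupr1 from 138.5 CPM ± 26.9 to 30.1 CPM ± 19.6 (SD, n = 4 each). Slc7a11, which encodes the cystine and glutamate antiporter, fell (-1.59, SE 0.26), as did Rcan2, a regulator of calcineurin (-1.56, SE 0.20), and Trpc6, a cation channel gene (-1.53, SE 0.25). Ociad2, Oca2, Dnase1, R3hdml, Adamts18, Erich5 and Tecrl fell by log2 values between -1.21 and -1.40. The smallest p-values among falls included those of Trim9 (-1.08, adjusted p = 0.000437), Adamts18, Ociad2 and Rnf113a1 (-0.93). Of these 24 genes with the largest changes, 19 were called in all 8 fits that leave out 1 library. The exceptions were Gcg and R3hdml, called again only without CKO c (adjusted p otherwise up to 0.108 and 0.116), Ngfr (without any library but control c and CKO b, up to 0.116), Nupr1 (without control d or CKO d, up to 0.0515) and Erich5 (without control d or CKO a, up to 0.0715).

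The genotypes did not overlap for 1490 of the 1706 changed genes. Over all tested genes this held for 16.3%, where chance gives 2.86%. The count of changed genes depended on single libraries: it was 503 without control d, 651 without CKO d, 780 without control b, 846 without CKO c and 2553 without control c. Removing the trends of each library on transcript length and GC content, an alternative chosen after the data were seen, gave 2661 of 14032 protein-coding genes, of which 50.4% were higher. The same 14032 genes with the trends left in, also fitted later, gave 1713, of which 1028 were higher, against 1055 of the 1706.

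Some transcripts of the fiber cell program were lower in CKO lenses, while its transcription factors showed no common direction. Of 16 crystallin genes, which encode the main soluble proteins of lens fibers, 3 fell and none rose. Crygn fell by 0.62 (SE 0.13, adjusted p = 0.0157), Crybb2 by 0.92 (SE 0.22, adjusted p = 0.0273) and Cryab by 0.57 (SE 0.14, adjusted p = 0.0309), and the other 13 had fitted values below 0 as well. Crybb2 was rare, with means of 6.40 CPM in controls and 3.47 CPM in CKO lenses. Crygn and Cryab had means of 2908 and 1705.7 CPM in controls. Adjusted over the list alone, 5 fell. Cryaa (log2 fold change -0.33, adjusted p = 0.294) and Crybb1 (-0.40, adjusted p = 0.251), among the most abundant, did not pass. The list median was -0.38, with -0.08 in set 1 and -0.74 in set 2, and the camera adjusted p was 2.41e-05 (adjusted p = 0.504 with an estimated correlation). The gamma crystallin genes are close copies of each other, so their separate values are uncertain. Crystallins took 27.2% ± 1.78 of all gene counts in controls and 23.9% ± 3.21 in CKO lenses (SD, n = 4 each). The difference of -3.31 percentage points had an exact permutation p of 0.171 (two-sided), with -0.287 points in set 1 and -6.34 in set 2. The Cryab call ended without any library but control a or control c (adjusted p up to 0.122), that for Crybb2 without control a, control d, CKO a, CKO c or CKO d (up to 0.102), and that for Crygn without control b, control d or CKO d (up to 0.073), while Crybb1 passed without control c (adjusted p = 0.0273). The crystallin share difference shrank to -2.15 points without CKO c.

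Of 24 genes for fiber structure, membranes and maturation, 8 fell and none rose, with 9 falls adjusted over the list alone. They included Lctl, a membrane-anchored glycosidase family gene of the lens (-0.68, SE 0.13, adjusted p = 0.00899), Caprin2, which encodes an RNA-binding protein of fibers (-0.60, SE 0.12, adjusted p = 0.0102), the actin regulator gene Cap2 (-0.45, SE 0.09, adjusted p = 0.0111) and the adhesion molecule gene Nrcam (-0.52, SE 0.12, adjusted p = 0.023). Values for Mip (-0.30, adjusted p = 0.195), Bfsp1 (-0.22, adjusted p = 0.538) and Bfsp2 (-0.20, adjusted p = 0.483), the lens aquaporin and the beaded filament genes, did not pass. The list had a median of -0.37 (-0.29 in set 1 and -0.55 in set 2) and a camera adjusted p of 2.66e-06 (adjusted p = 0.159 with an estimated correlation). Its mean log2 CPM overlapped between the genotypes (exact permutation p = 0.114, adjusted p = 0.264 over the 30 lists). Control d and CKO d each carried several of these calls: without control d the calls for Caprin2, Cap2 and Nrcam ended, as they did without CKO d (adjusted p up to 0.0552, 0.0565 and 0.0818). The calls for Cap2 and Nrcam ended without control b too, and that for Nrcam without CKO b or CKO c.

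Of 12 genes for transcription factors of fiber differentiation only Mafg, a small Maf gene, passed (-0.42, SE 0.11, adjusted p = 0.0347), with 2 rises and 2 falls adjusted over the list alone, and the camera adjusted p was 0.942. Prox1, Maf and Sox1 had log2 fold changes of -0.06 each (adjusted p 0.837 to 0.849), Pitx3 of 0.09 (adjusted p = 0.733), Hsf4 of -0.30 (adjusted p = 0.284) and Gata3 of 0.73 (adjusted p = 0.0812). The Mafg call ended without any library but control c (adjusted p up to 0.124). Without control c, Hsf4 passed (adjusted p = 0.0197), as did Gata3 (adjusted p down to 0.0315), which passed without CKO b too. The standard errors of Prox1, Maf and Sox1 (0.15, 0.17 and 0.15) leave room for small changes of these genes.

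Lens epithelial genes moved in either direction. Of 23 tested, 2 rose, among them the receptor gene Notch2 (0.74, SE 0.12, adjusted p = 0.00394). The 4 that fell included Wnt7b, a Wnt ligand gene (-0.81, SE 0.15, adjusted p = 0.00936), the laminin receptor subunit gene Itga6 (-0.55, SE 0.11, adjusted p = 0.0108) and the matrix gene Npnt (-0.75, SE 0.16, adjusted p = 0.0173). Foxe3, a transcription factor gene of the lens epithelium, had a value of 0.61 (adjusted p = 0.0517) and Pax6 of 0.13 (adjusted p = 0.537). Adjusted over the list alone, 5 rose and 7 fell, and the camera adjusted p was 0.579. Of 17 genes of the lens capsule and basement membrane, the collagen IV genes Col4a5 (-0.68, SE 0.11, adjusted p = 0.00359) and Col4a6 (-0.46, SE 0.11, adjusted p = 0.0274) fell and 15 did not pass (1 rise and 2 falls over the list alone, camera adjusted p = 0.249). The Itga6 and Npnt calls ended without control d (adjusted p 0.0579 and 0.0771), that of Npnt without CKO a too, and that of Col4a6 without any library but control c (up to 0.108). Foxe3 passed without control c or CKO a (adjusted p down to 0.0277).

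Cell cycle transcripts were higher in CKO lenses. Of 30 genes, 11 rose and none fell, and 17 rose adjusted over the list alone. Ccne1, the cyclin of the entry into DNA replication, rose by 1.37 (SE 0.14, adjusted p = 0.000565), from 14.9 CPM ± 2.13 to 39.4 CPM ± 10.8 (SD, n = 4 each). The centromere protein genes Cenpf and Cenpe rose by 0.64 (SE 0.11, adjusted p = 0.00697) and 0.46 (SE 0.08, adjusted p = 0.00882) and Birc5, which acts in chromosome segregation, by 0.57 (SE 0.10, adjusted p = 0.00786). Mki67 (0.34, adjusted p = 0.0597) and Ccnd1 (0.21, adjusted p = 0.358) did not pass. The list median was 0.33 (0.32 in each set) and the camera adjusted p 4.29e-09 (adjusted p = 0.0609 with an estimated correlation). The call for Cenpe ended without CKO d (adjusted p = 0.0549), and Mki67 passed without control a (adjusted p = 0.0431).

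Inhibitors of the cell cycle moved in either direction. Of 7 genes for inhibitors of cyclin-dependent kinases, Cdkn1a (p21) rose by 0.97 (SE 0.16, adjusted p = 0.00498) and Cdkn2d (p19) by 0.46 (SE 0.11, adjusted p = 0.0273), while Cdkn1b (p27), a gene of fiber cell exit from the cycle, fell by 0.44 (SE 0.11, adjusted p = 0.0271). Cdkn1c (p57) had a value of -0.11 (adjusted p = 0.676). The counts were the same adjusted over the list alone, and the camera adjusted p was 0.247. Of 24 target genes of p53, 7 rose and none fell (the same over the list alone), including Trp53inp1 (0.86, SE 0.12, adjusted p = 0.00196), Cdkn1a, Ddit4 (0.79, SE 0.14, adjusted p = 0.00806) and Pidd1 (0.60, SE 0.13, adjusted p = 0.0171). The p53 list had a median of 0.21 and a camera adjusted p of 0.0012 (adjusted p = 0.487 with an estimated correlation). The calls for Cdkn1b and Cdkn2d each ended without 6 of the 8 libraries (adjusted p up to 0.116 and 0.107), all but control a and control c for the first and all but control c and CKO b for the second. The Ddit4 call ended without control d (0.0501), and the Pidd1 call without control d, CKO c or CKO d (up to 0.0782).

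**Figure D2:**
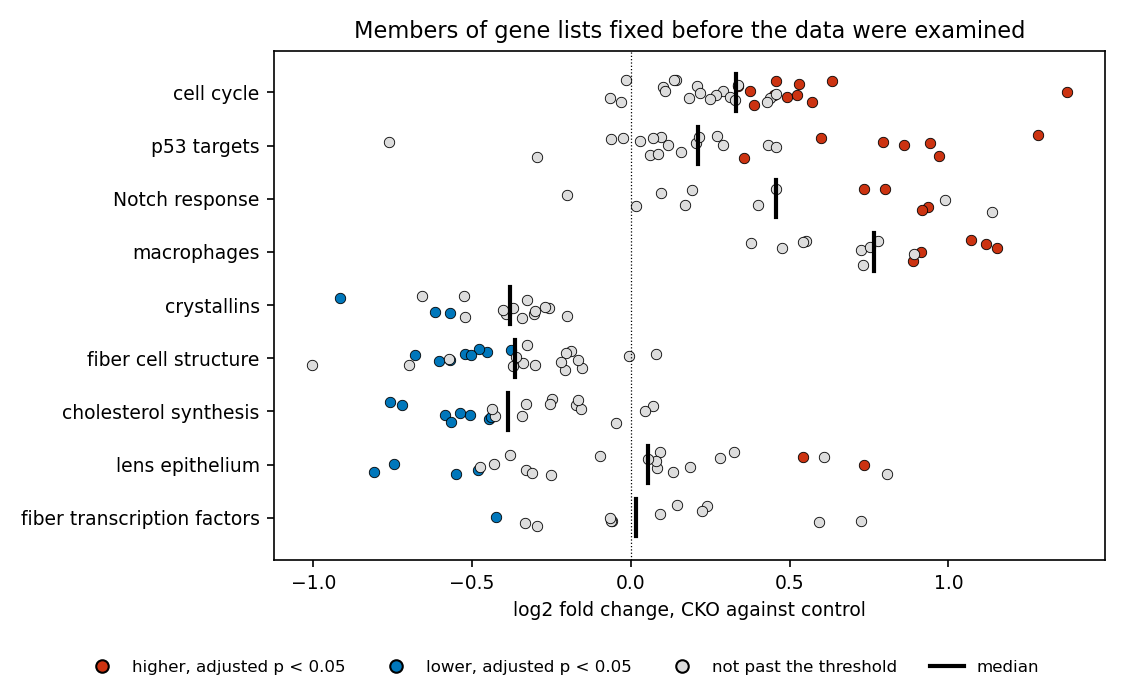
Fitted log2 fold changes (CKO against control) of every tested member of 9 gene lists fixed before the data were examined, with 1 point per gene, coloured where the adjusted p was under 0.05 (red higher, blue lower, grey not past), spread vertically for visibility only, and a black bar at the list median. The median was 0.33 for cell cycle genes, -0.38 for crystallins and 0.02 for fiber transcription factors.

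Genes of Notch signalling were higher in CKO lenses. Of 13 tested, 4 rose, 7 adjusted over the list alone, and none fell. The target gene Hey1 rose by 0.94 (SE 0.11, adjusted p = 0.000773), the receptor genes Notch3 by 0.92 (SE 0.11, adjusted p = 0.00118) and Notch2 by 0.74, and the feedback inhibitor gene Nrarp by 0.80 (SE 0.19, adjusted p = 0.0233). The list median was 0.46 and the camera adjusted p 1.33e-05 (adjusted p = 0.159 with an estimated correlation). Among 14 BMP and TGF-beta response genes, Msx2 (1.37, SE 0.16, adjusted p = 0.000848), Smad7 (1.01, SE 0.15, adjusted p = 0.00281) and Id3 (0.52, SE 0.13, adjusted p = 0.028) rose and the ligand gene Bmp7 fell (-0.76, SE 0.16, adjusted p = 0.0162), with 7 rises and 3 falls adjusted over the list alone. Its camera adjusted p was 0.0311 (adjusted p = 0.319 with an estimated correlation). Of 18 FGF and ERK response genes, Spred3 (1.31, SE 0.17, adjusted p = 0.00182), Spred2 (0.69, SE 0.09, adjusted p = 0.00196) and Etv4 (0.74, SE 0.15, adjusted p = 0.0133) rose, with 4 rises and 2 falls over the list alone and a camera adjusted p of 0.0755. Spred proteins restrain ERK signalling. None of 10 Wnt response genes passed, with either adjustment (camera adjusted p = 0.797). The call for Nrarp ended without control d, CKO b or CKO d (adjusted p up to 0.0926), those for Bmp7 and Etv4 without control d (0.069 and 0.0658), and that for Id3 without any library but control c or CKO a (up to 0.111). The BMP and TGF-beta list was no longer called without control a or CKO b (adjusted p up to 0.111), and the FGF and ERK list was called without control b, CKO a or CKO b (adjusted p down to 0.0278).

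Genes of cholesterol synthesis and uptake were lower in CKO lenses. Of 20 genes, 8 fell, 10 adjusted over the list alone, and none rose. Idi1 fell by 0.76 (SE 0.11, adjusted p = 0.00241), Hmgcs1 by 0.72 (SE 0.11, adjusted p = 0.00309), Sqle by 0.51 (SE 0.09, adjusted p = 0.00838) and Cyp51 by 0.54 (SE 0.10, adjusted p = 0.00991), all enzymes of the pathway. The list median was -0.39 (-0.34 in set 1 and -0.46 in set 2) and the camera adjusted p 1.01e-07 (adjusted p = 0.159 with an estimated correlation). The Cyp51 call ended without CKO d (adjusted p = 0.0505).

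Stress programs gave mixed results. Of 20 genes of the integrated stress response, Slc7a11 (-1.59), Nupr1 (-2.42) and Vldlr (-0.47, SE 0.09, adjusted p = 0.011) fell and Ddit4 (0.79) rose, with 5 falls and 1 rise over the list alone. The list median was -0.28 (-0.47 in set 1 and 0.00 in set 2), and the camera adjusted p was 0.0243 (adjusted p = 0.568 with an estimated correlation). Of 15 genes of the unfolded protein response, the chaperone genes Pdia4 (0.64, SE 0.11, adjusted p = 0.00647) and Hspa5 (0.44, SE 0.11, adjusted p = 0.032) rose and Herpud1 fell (-0.47, SE 0.13, adjusted p = 0.0445), as they did over the list alone (camera adjusted p = 0.904). Among 20 genes of autophagy and mitophagy only Bnip3l passed (-0.38, SE 0.11, adjusted p = 0.0478), none over the list alone, while 18 had fitted values below 0 and the camera adjusted p was 0.0178 (adjusted p = 0.504 with an estimated correlation). Irf9 rose (0.77, SE 0.12, adjusted p = 0.00311) as the only call among 21 interferon response genes (camera adjusted p = 0.625), Ndrg1 fell (-0.59, SE 0.14, adjusted p = 0.0259) as the only call among 22 hypoxia and glycolysis genes (camera adjusted p = 0.797), and Klf6 fell (-0.50, SE 0.10, adjusted p = 0.0107) as the only call among 17 immediate early and heat shock genes (camera adjusted p = 0.348), each with the same count over the list alone. Without control d the calls for Vldlr and Ddit4 ended (adjusted p 0.0551 and 0.0501), and without control d or CKO d those for Nupr1 and Klf6 (up to 0.0515 and 0.0543). Those for Hspa5 and Herpud1 ended without any library but control c or CKO c (up to 0.122 and 0.176), that for Bnip3l without any but control a, control c or CKO a (up to 0.163), and that for Ndrg1 without any but control a, control c or CKO b (up to 0.0979). The integrated stress response list was no longer called without control b or CKO a (adjusted p up to 0.176), while the interferon list was called as higher without control c (adjusted p = 0.0135) and the immediate early list as lower without CKO b (adjusted p = 0.0395). The medians of the interferon (-0.11) and Wnt (-0.04) lists lay below 0 where the test pointed up, and that of the lens epithelium (0.05) above 0 where it pointed down.

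Markers of other cell types that an eye dissection can carry over were measured in the same way. Macrophage markers were higher in CKO lenses: 5 of 14 rose, 9 adjusted over the list alone, and all 14 had fitted values above 0. They included the protease gene Ctss (1.15, SE 0.20, adjusted p = 0.00671) and the complement genes C1qc (1.12, SE 0.21, adjusted p = 0.00968), C1qa (1.07, SE 0.22, adjusted p = 0.0136) and C1qb (0.89, SE 0.22, adjusted p = 0.0281), none of them above a mean of 10.1 CPM in either genotype. The list median was 0.77, with 1.33 in set 1 and 0.40 in set 2, and the camera adjusted p 2.95e-06 (adjusted p = 0.487 with an estimated correlation). In set 1 the medians of endothelium and pericytes (0.92) and of erythroid cells (0.79) were above 0 too, and in set 2 they were -0.56 and -1.52. The mean log2 CPM of the list was higher in every CKO library than in any control (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.107 over the 30 lists). The C1qa and C1qb calls ended without control b or control d, and that of C1qb without control a, CKO a, CKO b or CKO d too (adjusted p up to 0.0626 and 0.108).

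Retinal transcripts were present in some libraries of either genotype. The mean log2 CPM of the retinal list stood at 2.27, -1.34, -0.25 and -0.68 in control replicates a to d and at 0.67, 1.32, 2.83 and -0.13 in the CKO replicates. None of 19 retinal genes passed, with either adjustment (median 0.74, with -0.52 in set 1 and 1.90 in set 2, camera adjusted p = 0.154). Without control a, Lhx2, Six6 and Rax, transcription factor genes of the early retina, passed (adjusted p 0.0399, 0.0435 and 0.0185). Of 9 genes of pigment epithelium and melanocytes only Oca2 passed (-1.37, SE 0.25, adjusted p = 0.00786), with the same result over the list alone. It went against the list, where 7 of 9 fitted values lay above 0 and the median was 0.81 (0.83 in set 1 and 1.36 in set 2, camera adjusted p = 0.507). Pmel (1.41, SE 0.47, adjusted p = 0.104) and Tyr (1.72, SE 0.67, adjusted p = 0.133) did not pass, nor did Tyrp1 (adjusted p = 0.123). Without CKO b, Pmel (1.71, adjusted p = 0.0107) and Tyrp1 (2.38, adjusted p = 0.0285) passed as higher. Of 15 periocular mesenchyme genes, Fbn1 (0.58, SE 0.12, adjusted p = 0.0138) and Col5a1 (0.44, SE 0.12, adjusted p = 0.0438) rose (the same 2 over the list alone, camera adjusted p = 0.904). No gene passed, with either adjustment, among 14 of endothelium and pericytes (camera adjusted p = 0.58), 12 of erythroid cells (0.348) or 10 of surface and corneal epithelium (0.808). With either adjustment, none passed among 11 of skeletal muscle (camera adjusted p = 0.0755). Nor did any of the 5 tested genes in the list that joins Xist with Y-linked genes (camera adjusted p = 0.662). Xist and the Y-linked genes mark opposite sexes, so the camera test of their joint list cannot show a difference in sex. Single omissions brought calls of whole lists: the retinal list without control a, CKO a or CKO d (adjusted p down to 2.65e-06), muscle without control b, control d, CKO b or CKO d (2.24e-07), the erythroid list without control b or CKO b (0.00244), endothelium without control c (0.00418) and pigment epithelium without CKO b (0.0321). The retinal, endothelial and pigment lists were higher and the muscle and erythroid lists lower in these fits. The periocular mesenchyme list had a median of -0.17 where the test pointed up. With control a and CKO c left out, the 2 libraries with the most retinal transcripts, 462 genes passed, 448 of them among the 1706. The Fbn1 call ended without control b, control d or CKO d (adjusted p up to 0.0607), and that for Col5a1 without any library but control a or control c (up to 0.166).

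**Figure D3:**
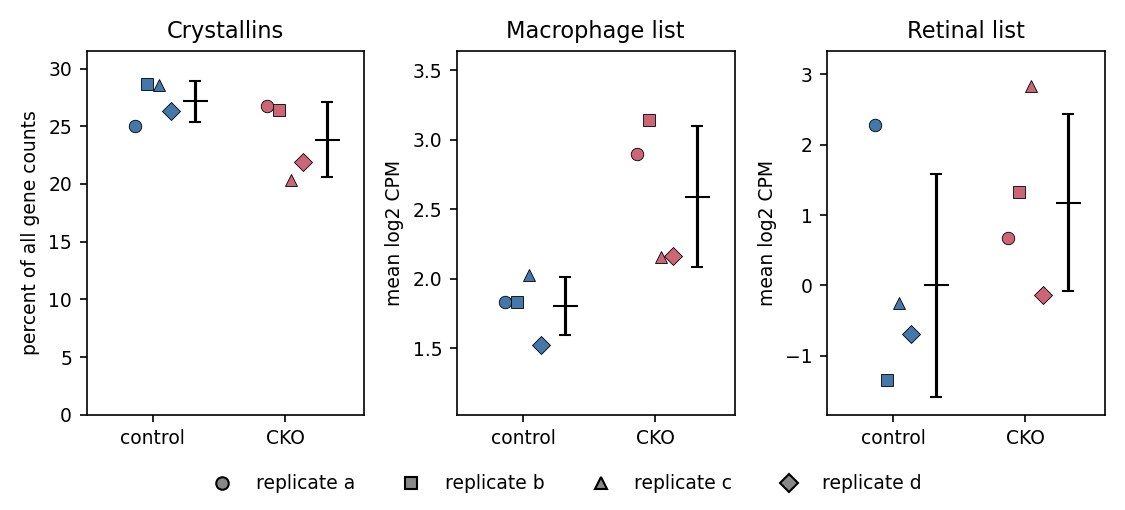
Crystallin share of all gene counts (percent, axis from 0) and mean log2 CPM of the macrophage and the retinal list in each library, with 1 point per library, the marker giving the replicate letter, and bars giving the mean ± SD of 4 libraries. The crystallin share was 20.4% in CKO c and 28.7% in control b, the macrophage list lies higher in every CKO library than in any control, and the retinal list is highest in CKO c (2.83) and control a (2.27).

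The genotype effect was compared between the 2 sets, which share no libraries. Across genes, the log2 fold changes fitted in set 1 and in set 2 had a Pearson correlation of 0.288 and a Spearman correlation of 0.252, and 59.8% of the genes had the same sign. Genes are not independent replicates, so no p-value is given. Over the 1706 changed genes, which were chosen on the libraries of both sets, the correlation was 0.887. The test of the difference between the sets called 0 genes with edgeR (smallest adjusted p = 0.172), 2662 genes had an unadjusted p under 0.05 (16.4%), and DESeq2 called 609. Without control d, edgeR called 1984.

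**Figure D4:**
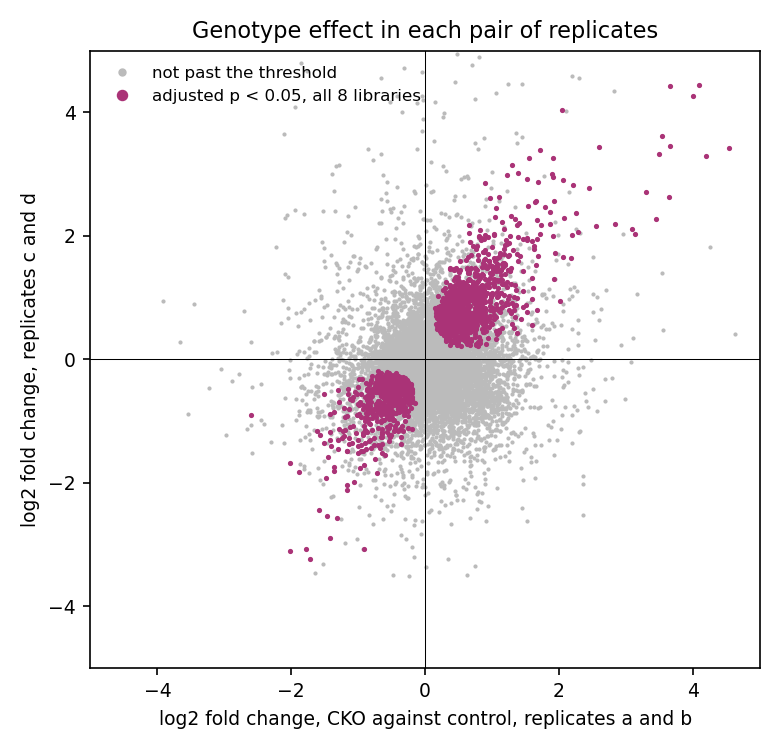
Log2 fold changes (CKO against control) fitted in replicates a and b (horizontal axis) and in replicates c and d (vertical axis), with 1 point per tested gene, in purple where the adjusted p over all 8 libraries was under 0.05. Both axes end at a log2 fold change of 5 in either direction and leave out 14 genes, and the Pearson correlation over all tested genes was 0.288.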

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

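The tests of the interaction with estimated correlations, of length and GC trends for the difference between the sets, of the share of fiber cells, of carried-over retinal tissue and of genotype for the crystallin and retinal patterns were chosen after the results were seen. Within each genotype, 398 groups of 4 libraries were examined for a library far from the other 3, and 19 (4.77%) held one. Chance alone marks about 1 in 20 such groups, so their total is no higher than chance would give. They were not spread evenly over the libraries, and control c stood apart most often. Pairs of controls that include control c had a chi-square per degree of freedom of 74.6 to 84.3. The other control pairs had 15.3 to 29.4, and the CKO pairs 22.1 to 102. The total therefore does not show that control c is like the other controls.

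Crystallin transcripts were lower in CKO lenses mainly in set 2, where the list median was -0.74 against -0.08 in set 1, a difference of -0.66 (camera test of the interaction, adjusted p = 7.6e-09, or 0.533 with an estimated correlation). The transcripts are short (median 781 nt against 3041 nt for all genes), but with each library's trends on length and GC content removed the median in set 2 stayed at -0.63 (over library means -0.58, SE 0.11), which argues against these trends as the whole source of the fall in set 2. For the difference between the sets the trends stay open, since with them removed the median in set 1 was -0.23 and the difference shrank to -0.40 (over library means -0.30, SE 0.16). A lower share of fiber cells would raise the markers of other cell types alike and stays open: in set 2 the mean was -0.60 for mesenchyme, -0.59 for the endothelial list, 0.03 for lens epithelium and 0.38 for macrophages, but both falls came from control c (endothelial mean log2 CPM 5.48, against 4.35 in control d and 4.24 in CKO c), and CKO d lay above control d. A difference between the genotypes stays open: the mean log2 level of the list gave an exact permutation p of 0.0571 over the 8 libraries. Scaling factors made without the crystallin and erythroid genes left the list median at -0.39, against -0.38.

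Retinal transcripts stood high in control a (mean log2 CPM of the list 2.27) and CKO c (2.83) and low in control b (-1.34), and the genotype difference of the list was larger in set 2 than in set 1 by 2.43 (medians 1.90 and -0.52, camera adjusted p = 0.0316, or 0.706 with an estimated correlation). Retinal tissue carried over with the lens may account for this, since members of the list followed each other across libraries with a median pairwise Spearman correlation of 0.667. That value lies between the bounds that had been set for and against, so this source stays open. A difference between the genotypes is not excluded either, with an exact permutation p of 0.286 for the list, and control a lies above 3 of the 4 CKO libraries.

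Other lists passed the camera test of the interaction at the preset correlation. With correlations estimated for each list, 0 of the 13 lists that passed did so (adjusted p 0.533 to 0.706). The difference of set 2 from set 1 in median log2 fold change was 0.29 for the m6A writer complex (adjusted p = 0.029), 0.20 for m6A readers and erasers (0.0112), 0.35 for fiber transcription factors (0.0265), 0.12 for lens epithelium (0.0451), 0.11 for FGF and ERK response (0.029) and 0.47 for the integrated stress response (0.00682). It was -1.35 for the interferon response (0.0233), -0.49 for immediate early and heat shock genes (0.0451), -1.48 for endothelium and pericytes (2.82e-07), -2.31 for erythroid cells (0.00114) and -0.93 for macrophages (0.000487). The percent of counts in ribosomal protein genes moved in opposite directions in the 2 sets (0.965 points and -1.10 points, a difference of -2.06), as did the correlation of expression with transcript length (-0.19 and 0.286, a difference of 0.476), and neither difference was tested.

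Among library measures, erythroid genes took 0.42% of counts in CKO b (0.05 to 0.1% in the other CKO libraries) and ribosomal protein genes 5.50% in control c (4.07 to 4.26% in the other controls). The mean log2 CPM of the m6A writer list was 5.04 in control c (5.13 to 5.14 in the other controls) and that of the autophagy list 5.80 in control a (5.87 to 5.88).

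Among single genes, control c stood apart in log2 CPM for Ngfr (3.86, others 4.92 to 5.06), Sox1 (7.77, others 8.32 to 8.40), Wnt7b (7.77, others 8.47 to 8.58), Syvn1 (5.26, others 5.64 to 5.71), Rgs5 (6.58, others 5.67 to 5.75) and the Y-linked gene Kdm5d (2.94, others 4.54 to 4.85). Control d stood apart for Ythdf1 (6.11, others 5.81 to 5.84), Smad7 (3.55, others 3.74 to 3.78) and C1qa (1.97, others 2.21 to 2.24), and control b for Tyr (-4.21, others -1.82 to -1.34). Among CKO libraries, CKO c stood apart for Gcg (0.61, others 3.25 to 3.33) and Cryab (9.83, others 10.24 to 10.30), CKO a for Ociad2 (4.62, others 4.04 to 4.05) and Cyp51 (6.97, others 6.84 to 6.86), and CKO b for Tyrp1 (-2.89, others 0.78 to 0.84).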

How the results depend on the processing

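The removal of length and GC trends, the fit of the same genes with the trends left in and the omission of control a with CKO c were chosen after the data were seen, and the other alternatives before. The Mettl3 decrease passed in all 22 alternatives, with log2 fold changes between -1.13 and -0.85. No called gene changed sign under any alternative, and 41 values of genes that were not called did. Among the called lists, the median of m6A readers and erasers went from 0.02 to -0.00334 without CKO c, where the list was no longer called. Over the named genes, 3106 values kept their side of the threshold, 297 called ones lost it and 103 gained it, and over the lists 458, 32 and 20. The other scalings ended at most 3 of the 89 calls of named genes (RLE 3, TMM without crystallin and erythroid genes 2, upper quartile 0). The RLE scaling and that without crystallin and erythroid genes ended no call of a list, and upper quartile scaling was not run for lists. The filter at 1 CPM ended 2 list calls (m6A writers and BMP) and 0 of the 89, the replicate block 1 (m6A writers) and 26 of the 89, and the removal of trends 1 (BMP) and 0 of the 89. The fit without the set term ended 15 of the 89 and 0 list calls, set 1 alone 18 and set 2 alone 41, and the omission of control a with CKO c 35 and 3 list calls. Of these 89 calls, 52 passed in all 8 fits without 1 library.

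The count of changed genes was 1706. It was 1365 in set 1 alone (57.6% higher), 858 in set 2 alone (81.2% higher), 462 at an adjusted p under 0.01 and 100 in a test against a 1.5-fold change, the latter 2 by construction since they ask for more. It was 2579 with 1 surrogate variable, 2661 with length and GC trends removed over 14032 genes (1713 of the same genes with the trends left in), and 462 without control a and CKO c, where fewer libraries were fitted. Leaving out 1 library gave 503 (control d) to 2553 (control c) genes. Of the 12 lists called by camera, 0 passed with correlations estimated for each list, where fry called 9, and leaving out 1 library gave 10 to 16. The test of the difference between the sets, 0 genes with edgeR (2662 at an unadjusted p under 0.05), gave 609 with DESeq2 and 918 without a filter on low counts, and 0 to 1984 (control d) without 1 library. The difference in crystallin share, -3.31 points, lay between -4.28 and -2.15 points without 1 library and did not pass in any. The correlation between the sets, 0.288, was 0.887 over the changed genes, which were chosen on the libraries of both sets. Apart from the alternatives that ask for more or use fewer libraries or selected genes, the cause was not tested.

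With the replicate letter as a block, 665 genes were called (75.9% higher). Whether the letters pair the libraries is not known. Same-letter libraries correlated at -0.063, 0.092, -0.187 and 0.279 for a to d. Of the controls, only control d had its best match in the CKO library of its own letter. These correlations are too few and too weak to decide whether the letters pair. With 4 libraries per genotype, the simulated recovery of 1.5-fold changes was 16.4%, among 200 changed genes. The real fit called 1706 genes, with a median absolute log2 fold change of 0.62, so this rate does not carry over to it directly. Changes of this size may still be missed in these libraries.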

Other observations

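The tests of gene families, of genes near Mettl3, of each list over the splits and of the architecture with trends removed were chosen after results had been seen. Among transcription factor genes of the Sox family, 4 of 17 rose and none fell in CKO lenses (camera adjusted p = 0.0345 over 92 families, adjusted p = 0.51 with an estimated correlation). Beside Sox21 these were Sox11 (log2 fold change 1.48, adjusted p = 0.0322), Sox12 (0.77, adjusted p = 0.00469) and Sox4 (0.78, adjusted p = 0.0399), named after their values were seen. Of 40 Zbtb genes, which encode zinc finger proteins, 11 rose and 2 fell (adjusted p = 0.00178, adjusted p = 0.826 with an estimated correlation). Of 28 genes whose symbols begin with Ap and a number or subunit code, many of them for adaptor complexes of vesicle transport, 5 fell (adjusted p = 0.00178, adjusted p = 0.51 with an estimated correlation). In all, 9 of 92 families were called and 0 with estimated correlations.

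Sall2, a zinc finger gene beside Mettl3 (chromosome 14, 52311172 to 52328762), rose by 0.98 (SE 0.10, adjusted p = 0.00057). It was the only call among 15 tested genes within 1 Mb of Mettl3, where 10.5% of all tested genes were called (Fisher's exact p = 1). With so few genes this test has little power. It cannot tell whether the rise of Sall2 is a local effect of the changed Mettl3 allele. Rbmx, the X-linked relative of Rbmxl1, fell by 0.84 (SE 0.10, adjusted p = 0.00111) while Rbmxl1 rose, and reads shared between the copies leave both values uncertain. Xist stood at 300, 320, 1094 and 439 CPM in controls a to d and at 447, 121, 0.369 and 941 CPM in CKO a to d. Control c, with the most Xist, had the lowest level of the Y-linked gene Kdm5d among the controls. The mix of sexes may thus differ between libraries, those of set 2 included. Sex was not a term in the model, so its part in the differences was not tested.

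Genes that rose had a longer coding stretch within 1 exon (median 650 nt, n = 1027) than genes that fell (245 nt, n = 588) or did not pass (276 nt, n = 12417). Across 14032 genes the log2 fold change correlated with this length at 0.244, and at 0.210 given transcript length, coding length, GC content and mean expression, with 0.136 in set 1 and 0.211 in set 2. Bias of the libraries on GC content or length stays open. The correlation kept most of its size, and the lowest set value with the trends removed was 0.141, but neither settles the question. The condition set beforehand, that the value exceed every other split, was not met: other splits reached 0.214, 0.220 and 0.224. The value with the trends removed was not computed for the other splits. These splits keep 3 libraries of each genotype together, which does not explain values above that of the real split. The 17 splits that mix the genotypes evenly reached at most 0.141. Without the covariates, other splits reached up to 0.290 in absolute size, and evenly mixed ones up to 0.270, against 0.244. Loss of m6A, which lies away from exon junctions, is a candidate explanation that these counts cannot prove. The density of its sequence motif in such regions had an adjusted correlation of only 0.0262, under the bound set beforehand, so that prediction was not met.

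Other splits of the libraries were fitted in the same way. The real split gave 1706 genes and the highest of the others 4, so no other of the 34 splits gave as many. That makes chance less likely but does not exclude it, since 34 splits cannot give a share below 1 of 34. The other splits also keep the genotype difference within their groups. This widens their spread and lowers their counts, so the contrast of 1706 with 4 overstates the support. Some splits also hold unequal numbers of libraries from the sets. The count of called lists does not stand out: the real split gave 12, the highest other 17, and 13 of 34 gave as many. Single lists differed in this respect. The camera p-values of the cell cycle, Notch and cholesterol lists were reached by no other split, and that of the fiber structure list by 1 other. Those of the m6A writers were reached by 2 others, of the BMP and autophagy lists by 3 each, of p53 targets by 4 and of macrophages by 5. Those of the crystallins and of the m6A readers and erasers were reached by 7 others each, and that of the integrated stress response by 14.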
